A study of Mus musculus with 24 samples.

How the data were processed

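RNA of cells sorted from mouse small-intestine tumours of the AKVPL genotype was isolated with the RNeasy Micro kit and checked on a Bioanalyzer, and polyA RNA was sequenced, per the labels' protocols. Groups were formed from the labels: saline or diphtheria toxin (DT) at 24, 48 or 96 h, with 4 libraries in each of 6 groups. The authors deposited 1 table per library with 36528 gene rows, each with a count and a normalized value. The count is the number of reads aligned uniquely to a gene model, per the file headers, and it was used as deposited. The normalized value, nRPKM, is an RPKM adjusted by a size factor, per the file headers, and was used here only to recover the authors' size factors. Over 11889 genes with counts of at least 50, the deposited RPKM equalled the count times a gene factor and a library factor to a relative deviation of at most 9.5e-15. The submitters' processing notes name GSNAP and GRCm38; versions, annotation, counting options and use of strand are not given in the sources used here. Of the Entrez identifiers 31049 (85.0%) matched a RefSeq table of GRCm38.p6 and took their symbols from it. The 5479 unmatched identifiers held 1.29% to 1.52% of each library's counts and stayed in library sizes and tests.

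Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with robust dispersion, after scaling by TMM and filtering by expression within groups, which left 17468 genes. All 24 libraries entered 1 fit with a mean per group and 18 residual degrees of freedom, so that the groups shared an estimate of spread (common biological coefficient of variation 0.120). P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, two-sided. Standard errors of log2 fold changes were taken as the size of the change over the square root of F. CPM were computed with TMM library sizes. DT was compared with saline at each time, the DT effect among times by interaction tests, and saline libraries among times. The 33 gene lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01 between genes, then with an estimated correlation and with fry. Overlaps of calls were set beside the number for independent lists of the same sizes. The tests, gene lists, naming rule and most alternatives were chosen before the data were examined.

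The lists held Lgr5+ stem cell, Wnt target, reserve stem cell, fetal and regenerative epithelium, YAP target, S phase, G2/M, enterocyte, goblet, Paneth, enteroendocrine, tuft and gastric type epithelium genes. They also held type I interferon, interferon gamma and antigen presentation, NF-kB, antimicrobial, p53 target, stress response, EGFR and ERK, Notch, BMP and TGF-beta, hypoxia, cholesterol synthesis, immediate early and heat shock, EMT and epithelial identity genes. Markers of fibroblasts, endothelial cells, macrophages, neutrophils, T and NK cells and B cells completed them. Per comparison the rule named Lgr5, the 12 largest changes in each direction among called genes with an assigned symbol, at least 1 CPM in a group and no overlap of the 2 groups, and up to 4 members of each list with the smallest p. Of the list members it named, those printed are a part chosen after their values were seen. Unmatched identifiers, provisional symbols such as those starting with Gm or ending in Rik, microRNA and small nucleolar RNA symbols (all that start with Mir or Snor), pseudogenes and immune receptor segments had no assigned symbol in this sense and were passed over, also where their change was larger. For the interaction it named the 10 such genes with the smallest p. Some genes that the rule named are not reported here.

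Replicates of a group were compared first; the smallest chi-square per degree of freedom between any 2 was 3.97, so no library was a copy of another within sampling noise. The test was tried on simulated counts for 17309 genes with 200 changed at 24 h, drawn from genes with a mean of at least 1 CPM. It recovered 63% of 1.5-fold and 90% of 2-fold changes, with 4 false calls of 157, the right sign in 99.5% and a median absolute log2 error of 0.080. For the interaction it recovered 48% and 75%, with 4 false of 127, and in the unchanged 96 h comparison it made 0 calls, as did limma, while DESeq2 made 1. Alternatives were median-of-ratios and upper quartile scaling, 2 other filters, DESeq2 1.42.0, limma voom with quality weights, dispersion without robust estimation, a replicate block, a leukocyte score as covariate, only the libraries compared, a fold threshold, an adjusted p under 0.1 and each library left out. Scaling by the authors' size factors was added after seeing the data.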

Results

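Gene expression was measured by RNA sequencing in cells sorted from mouse tumours that were derived from small intestine and carry the genotype recorded as AKVPL. The tumours had received diphtheria toxin (DT), used in this design to deplete cells expressing Lgr5, a receptor that marks intestinal stem cells, or saline as the control. The sample names carry EpCAM, an epithelial surface protein, and the sort is recorded as bulk. Cells were taken at 24, 48 or 96 h, and each of the 6 groups holds 4 libraries, 24 in all. Total counts per library, in units of 1e6 counts, ran from 10.9 to 27.7. At 24 h they were 13.1 to 14.6 for saline and 11.3 to 27.6 for DT. At 48 h they were 15.6 to 27.6 and 10.9 to 27.7, and at 96 h 14.4 to 24.2 and 11.5 to 24.3. The labels do not say that the libraries of a group come from separate animals, so p-values measure the spread between these samples, which may be technical. After filtering, 17468 genes were tested. The first principal component held 35.2% of the variance and the second 20.4%. All saline libraries lay on the negative side of the first component. Replicate 3 of the DT group at 48 h lay at -0.82 on it, against 17.5 to 19.3 for the other DT libraries of that time.

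**Figure D1:**
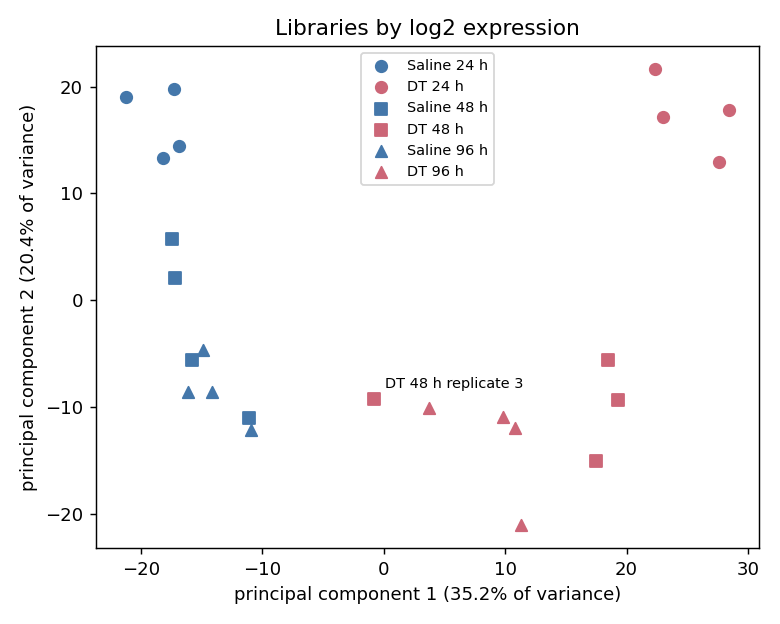
Principal components 1 (35.2% of the variance) and 2 (20.4%) of log2 expression over the 1000 most variable genes, 1 point per library, coloured by treatment with the time as marker shape. DT libraries of 24 h lie farthest to the right, and replicate 3 of the DT group at 48 h lies at -0.82 on component 1, between the saline libraries and the other DT libraries of its time.

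The targeted gene was examined first. Lgr5 (Entrez 14160; chromosome 10, 115450314 to 115587780 on GRCm38) had a mean of 200 ± 16.9 CPM (counts per 1e6 counts; SD, n = 4) in saline and 81.4 ± 3.72 CPM in DT libraries at 24 h. The fall was 1.30 ± 0.12 on the log2 scale (SE; edgeR quasi-likelihood test, adjusted p = 4.4e-08), a 2.46-fold difference. At 48 h the means were 182 ± 14.0 and 121 ± 35.2 CPM (log2 fold change -0.60 ± 0.12, adjusted p = 0.00272), and at 96 h 171 ± 13.7 and 127 ± 5.35 CPM (-0.43 ± 0.12, adjusted p = 0.0447). All 4 DT libraries lay below all 4 saline libraries at 24 and at 96 h. At 48 h, 3 DT libraries held 95.4, 98.7 and 117 CPM and replicate 3 held 171 CPM, inside the saline range of 164 to 198 CPM. Without that library the log2 fold change at 48 h was -0.80 (adjusted p = 2.1e-06). The Lgr5 call at 96 h was not kept with median-of-ratios size factors (adjusted p = 0.0570), with upper quartile scaling (0.0584), without a low-count filter (0.0655), with a leukocyte score as covariate (0.0572), with the authors' size factors (0.0545) or without any single library of that time (0.0612 to 0.152). The call at 48 h was not kept when only the libraries of 48 h were fitted (0.0663). The effect on Lgr5 itself differed among the times (interaction adjusted p = 0.00507), being smaller than at 24 h by 0.70 at 48 h (adjusted p = 0.0273) and by 0.86 at 96 h (adjusted p = 0.00232).

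**Figure D2:**
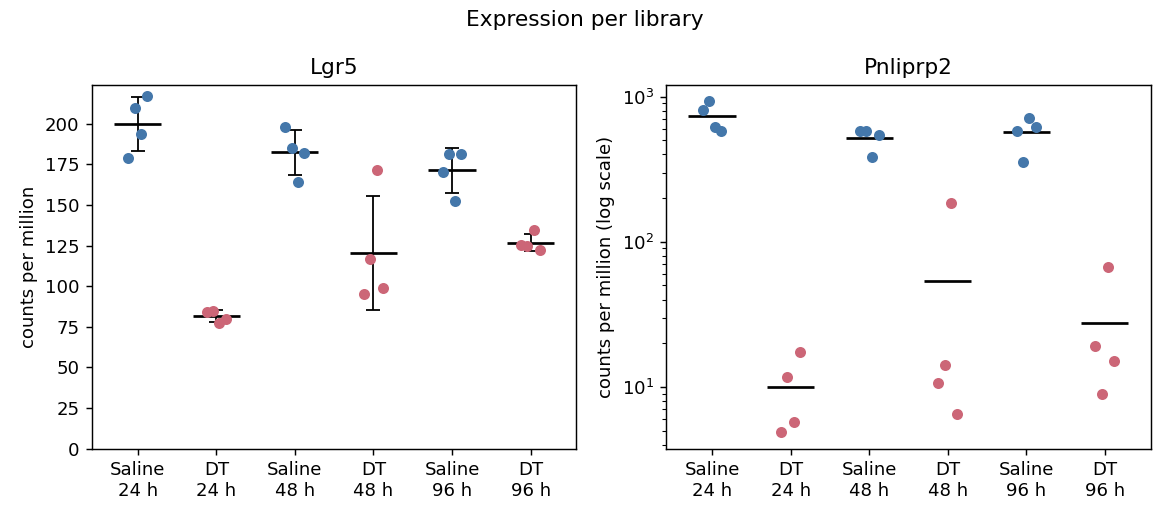
CPM of Lgr5 (linear axis from 0) and Pnliprp2 (log axis) in each library, by treatment and time; points are libraries, horizontal bars are group means, and error bars for Lgr5 are SD (n = 4). Mean Lgr5 was 81.4, 121 and 127 CPM in DT libraries at 24, 48 and 96 h, while Pnliprp2 had means of 9.91, 53.7 and 27.6 CPM in DT and 734, 522 and 567 CPM in saline libraries.

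The comparison at 24 h asked how the sorted cells differed 1 day after toxin. The G2/M, S phase and interferon lists were called higher in DT than in saline libraries. The goblet, Paneth, antimicrobial, Wnt target, cholesterol synthesis and hypoxia lists were called lower. Of these calls, those of the G2/M and type I interferon lists held with an estimated correlation (adjusted p = 0.0150 and 0.0250) and the others did not (0.0755 to 0.333). Of the 17468 genes, 3469 were higher and 3296 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 578 and 487 differed by at least 2-fold. The 12 largest increases under the rule for named genes were Cxcl9, a chemokine induced by interferon gamma (log2 fold change 4.94 ± 0.66, from 0.28 to 8.48 CPM), Ctrb1, a chymotrypsinogen (4.56 ± 0.62), and Oas3, an antiviral oligoadenylate synthetase (3.87 ± 0.24, from 2.11 to 30.9 CPM). Next came the TNF family ligand Tnfsf15 (3.82 ± 0.33), Ampd1 (3.81 ± 0.60), the mitochondrial uncoupling protein Ucp1 (3.73 ± 0.64) and Ak8 (3.66 ± 0.66). The others were the long noncoding RNA Trp53cor1 (3.52 ± 0.52), the lipoxygenase Aloxe3 (3.32 ± 0.32), the interferon-induced Ifit3 (3.31 ± 0.37), Amhr2 (3.19 ± 0.57) and Myo15 (3.10 ± 0.47). Apart from Oas3 these 12 had means below 10 CPM in both groups, and reads of Ifit3 and of the Oas1 genes may be divided among near-identical copies.

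The 12 largest decreases at 24 h under the same rule, which passes over genes without an assigned symbol, included abundant transcripts. Spock2, a secreted proteoglycan, went from 1145 ± 227 to 58.7 ± 25.5 CPM (SD, n = 4; log2 fold change -4.28 ± 0.48), and the lipase-related genes Pnliprp2 from 734 ± 166 to 9.91 ± 5.82 CPM (-6.18 ± 0.92) and Pnliprp1 from 583 ± 140 to 24.3 ± 12.1 CPM (-4.57 ± 0.63). Ms4a2, the beta chain of the high-affinity IgE receptor, went from 24.1 to 0.24 CPM (-6.49 ± 0.84). Lower too were Mt4, a metallothionein (-5.27 ± 0.66), the zinc finger gene Zfp831 (-5.12 ± 0.56), and the complement component C8b (-5.07 ± 0.66). Further down were Mat1a, a methionine adenosyltransferase (-4.88 ± 0.63), Slc44a5 (-4.87 ± 0.48), the bicarbonate cotransporter Slc4a5 (-4.53 ± 0.59), the noncoding RNA Snhg11 (-4.21 ± 0.59) and Ankfn1 (-4.03 ± 0.68). All 24 genes kept their call without each single library. The log2 fold change moved to 5.82 for Cxcl9 without saline replicate 2 and to 5.56 for Ctrb1 without saline replicate 4. It was 4.51 for Ucp1 and 4.98 for Ak8 without saline replicate 1, and -6.32 for Mt4 without DT replicate 4.

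Among the gene lists, those of dividing cells were higher throughout at 24 h. All 20 measured G2/M genes rose (20 also when adjusted over the list alone), with a median log2 fold change of 1.28 (camera adjusted p = 7.4e-40; adjusted p = 0.0150 with an estimated correlation). Examples are cyclin Ccnb2 (21.9 to 64.9 CPM, 1.57 ± 0.11), the kinesin Kif23 (1.28 ± 0.10) and the checkpoint kinase Bub1 (1.36 ± 0.11). All 22 S phase genes rose (22 adjusted over the list alone; median 0.86, camera adjusted p = 2.3e-23), though this call was not kept with an estimated correlation (adjusted p = 0.0755). They included Rrm2, a ribonucleotide reductase subunit, from 14.5 to 52.6 CPM (1.87 ± 0.18), Uhrf1 (1.34 ± 0.13) and the replication licensing factor Mcm3 (1.09 ± 0.11). Of 17 type I interferon response genes 16 rose and none fell (16 adjusted over the list alone; median 1.62, camera adjusted p = 8.3e-27, and adjusted p = 0.0250 with an estimated correlation). Among them were Isg15 (14.8 to 54.2 CPM, 1.88 ± 0.16) and Oasl2 (14.7 to 89.5 CPM, 2.61 ± 0.20). Of 17 interferon gamma and antigen presentation genes 10 rose and 2 fell (13 changed adjusted over the list alone; camera adjusted p = 5.5e-05, adjusted p = 0.259 with an estimated correlation), among them B2m, the light chain of class I molecules, from 215 to 528 CPM (1.29 ± 0.14), and the peptide transporter Tap1 (1.60 ± 0.17).

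Wnt target genes were lower at 24 h, with 12 of 21 falling and 1 rising (15 changed adjusted over the list alone; camera adjusted p = 3.6e-06, adjusted p = 0.104 with an estimated correlation). The Wnt inhibitors Nkd1 (1168 to 533 CPM, -1.13 ± 0.10) and Notum (807 to 331 CPM, -1.29 ± 0.12) fell, whereas the proliferation regulator Myc rose from 162 to 230 CPM (0.51 ± 0.07). Of 21 Lgr5+ stem cell genes 9 fell and 1 rose (10 changed adjusted over the list alone, camera adjusted p = 0.00570, adjusted p = 0.104 with an estimated correlation). Among them were Tnfrsf19 (-0.67 ± 0.10) and the Wnt receptor ligase Rnf43 (-0.45 ± 0.07). Both are also in the Wnt list, as are Lgr5, Ascl2, Znrf3 and Ephb3, so the 2 lists are not independent. The goblet and Paneth cell lists were also called lower, whereas the enteroendocrine and tuft cell lists were not called. Of 10 goblet cell genes 5 fell and 1 rose (6 adjusted over the list alone; camera adjusted p = 0.0337, adjusted p = 0.314 with an estimated correlation, and 0.0550 and 0.0685 without DT replicates 1 and 2). Examples were Fcgbp (340 to 90.1 CPM, -1.92 ± 0.24) and the mucin Muc2 (9.78 to 1.13 CPM, -3.09 ± 0.45). Of 10 Paneth cell genes 6 fell (6 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.333 with an estimated correlation). They included the lectin Itln1 (24.2 to 10.6 CPM, -1.19 ± 0.24) and the ribonuclease Ang4 (5.47 to 0.66 CPM, -3.15 ± 0.63). Of 8 antimicrobial genes 7 fell (7 adjusted over the list alone; camera adjusted p = 2.6e-04, adjusted p = 0.104 with an estimated correlation). Among them were the lectin Reg3b (118 to 17.8 CPM, -2.70 ± 0.45) and the oxidase Duox2 (8.83 to 3.65 CPM, -1.25 ± 0.22). Pla2g2a, Ang4 and Itln1 are in both the antimicrobial and the Paneth list, so these 2 lists are not independent at any time.

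The cholesterol synthesis, hypoxia, immediate early, BMP and EGFR lists were also called lower at 24 h. Of 20 cholesterol synthesis genes 16 fell and 1 rose (18 changed adjusted over the list alone; camera adjusted p = 1.9e-08, adjusted p = 0.108 with an estimated correlation). Examples were the sterol sensor Insig1 (88.9 to 47.1 CPM, -0.92 ± 0.08) and the synthase Hmgcs1 (271 to 159 CPM, -0.77 ± 0.09). Of 15 hypoxia and glycolysis genes 11 fell (12 adjusted over the list alone; camera adjusted p = 2.8e-05, adjusted p = 0.314 with an estimated correlation). They included the angiogenic factor Vegfa (368 to 173 CPM, -1.09 ± 0.12) and the glucose transporter Slc2a1 (405 to 246 CPM, -0.72 ± 0.11). Of 14 immediate early and heat shock genes 11 fell (11 adjusted over the list alone; camera adjusted p = 1.2e-06, adjusted p = 0.129 with an estimated correlation). Among them were Fos (1349 to 882 CPM, -0.61 ± 0.07) and Atf3 (830 to 456 CPM, -0.87 ± 0.10). Of 9 BMP and TGF-beta target genes 7 fell (8 adjusted over the list alone; camera adjusted p = 6.3e-05, adjusted p = 0.0755 with an estimated correlation). Examples were the helix-loop-helix inhibitors Id1 (-0.71 ± 0.13) and Id3 (-0.84 ± 0.12). Of 16 EGFR ligand and ERK feedback genes 10 fell (10 adjusted over the list alone; camera adjusted p = 0.00467, adjusted p = 0.268 with an estimated correlation). They included Etv5 (-0.41 ± 0.08), the phosphatase Dusp4 (-0.33 ± 0.07) and the ligand Hbegf (-0.47 ± 0.11). Egr1 is in both the EGFR and the immediate early list. Atf3 is in both the immediate early and the stress response list, so these lists are not independent at any time.

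Several lists had members that moved in both directions at 24 h, with no call for the list. Of 17 fetal and regenerative epithelium genes 7 rose and 4 fell (camera adjusted p = 0.452), with Ly6a (119 to 397 CPM, 1.73 ± 0.18) and the annexin Anxa1 (326 to 576 CPM, 0.82 ± 0.09) higher and Ctse (-0.77 ± 0.10) lower. YAP target genes had 3 higher and 3 lower of 11, among them Ankrd1 (1.19 ± 0.18), and their median was -0.13 while the mean was 0.02 and the test direction up (camera adjusted p = 0.812). The integrated stress and unfolded protein response list had 4 higher, such as the serine synthesis gene Psat1 (1.23 ± 0.10) and Atf4 (0.45 ± 0.08), and 7 lower of 15. The counts higher and lower were 1 and 3 of 7 reserve stem cell genes, 4 and 3 of 17 tuft cell genes and 2 and 2 of 16 enteroendocrine cell genes. They were 1 and 0 of 14 enterocyte genes, 4 and 1 of 11 gastric type epithelium genes and 3 and 1 of 17 NF-kB and inflammatory genes. For p53 target genes they were 3 and 6 of 15 (called lower without saline replicate 2, adjusted p = 0.0378, or DT replicate 3, 0.0447). By fry the p53 (8.6e-04) and reserve stem cell (0.00104) lists were called lower. The counts were 1 and 1 of 9 Notch pathway genes and 0 and 1 of 8 EMT genes. Epithelial identity genes had 3 higher, with Krt18 (2190 to 2823 CPM, 0.37 ± 0.08), and 4 lower of 10, with Epcam (1587 to 1323 CPM, -0.26 ± 0.06). For epithelial identity the median (0.02) and mean (0.01) lay above 0 and the test direction was down, and for Notch the median was -0.05, the mean 0.06 and the direction up. Adjusted over the list alone, 11 of the fetal, 7 of the YAP, 12 of the stress, 5 of the reserve stem and 7 of the tuft genes changed. So did 3 of the enteroendocrine, 0 of the enterocyte, 6 of the gastric, 3 of the NF-kB, 11 of the p53, 2 of the Notch, 0 of the EMT and 7 of the epithelial identity genes.

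Markers of other cell types were present in these sorted libraries at 24 h. Of 12 fibroblast markers 2 were called higher, Dcn (40.5 to 78.8 CPM, 0.96 ± 0.32) and Pdgfra (0.53 ± 0.21), and the call was lost for Dcn without saline replicate 4 (adjusted p = 0.0548) or DT replicate 2 (0.0630) and for Pdgfra without saline replicate 2, 3 or 4 or DT replicate 1 or 4 (0.0639 to 0.229). Pdgfra also lost it without a low-count filter, with the leukocyte score as covariate and with only the libraries of 24 h (0.0554 to 0.109). The list's median log2 fold change was 0.50 (camera adjusted p = 0.322), beside the medians of 1.28 for G2/M and 1.62 for interferon genes. Of 8 endothelial markers 1 was higher. No macrophage and monocyte marker of 12, no neutrophil marker of 4 and no B and plasma cell marker of 1 was called, and 1 of 4 T and NK cell markers was lower. The macrophage list had a median of 0.17 and a mean of 0.10 with the test direction down, and the T and NK list a median of 0.18 and a mean of -0.24. Adjusted over the list alone, 0 fibroblast, 1 endothelial, 0 macrophage, 0 neutrophil, 1 T and NK and 0 B cell markers changed.

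**Figure D3:**
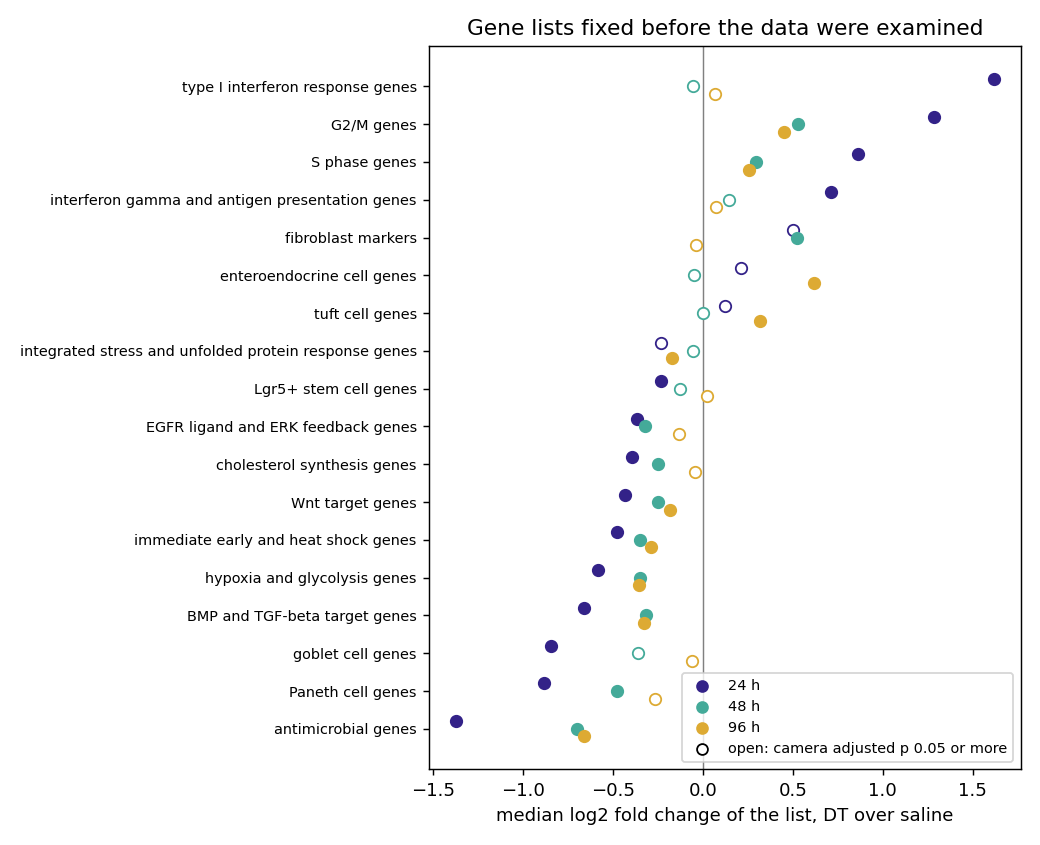
Median log2 fold change (DT over saline) of each gene list called at 1 or more times, at 24, 48 and 96 h; filled points have a camera adjusted p under 0.05 and open points do not. The type I interferon list has a median of 1.62 at 24 h, -0.06 at 48 h and 0.07 at 96 h, while the G2/M list has 1.28, 0.53 and 0.45.

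At 48 h the same contrast gave 844 higher and 1135 lower genes, 72 and 223 of them by at least 2-fold. The 12 largest increases under the naming rule were in low transcripts: Dnah10 (2.53 ± 0.49), Tnfsf15 (2.43 ± 0.31), the bone matrix protein gene Ibsp (1.95 ± 0.52), Btn1a1 (1.85 ± 0.32), and Aloxe3 (1.78 ± 0.31). They were followed by A3galt2 (1.75 ± 0.21, from 2.44 to 8.13 CPM), Hmcn2 (1.69 ± 0.43, from 3.96 to 12.5 CPM), the granzyme Gzmd (1.56 ± 0.49), Zglp1 (1.51 ± 0.35), Fbxo17 (1.48 ± 0.32), Ephx3 (1.47 ± 0.33) and Phgr1 (1.33 ± 0.24). The 12 largest decreases under it were Ms4a2 (-3.79 ± 0.69, from 18.2 to 1.45 CPM), the cytochrome Cyp2e1 (-3.66 ± 0.71), C8b (-3.56 ± 0.62), Zfp831 (-3.43 ± 0.47), and Mt4 (-3.36 ± 0.58). After these came Pnliprp2 (-3.29 ± 0.79, from 522 to 53.7 CPM), Slc44a5 (-3.07 ± 0.42), Mat1a (-3.04 ± 0.54), Msx3 (-2.94 ± 0.51), Hsd17b13 (-2.89 ± 0.48), the defensin Defa24 (-2.88 ± 0.82) and Ankfn1 (-2.83 ± 0.57). Defa24 and Gzmd belong to families of near-identical copies whose reads may be divided between them. Calls were lost for Ibsp without saline replicate 1 or 4 or DT replicate 2 or 4 (adjusted p = 0.0568 to 0.0638) and for Hmcn2 without DT replicate 4 (0.117). They were also lost for Gzmd without any saline library or DT replicate 1 or 4 (0.0603 to 0.213) and for Defa24 without saline replicate 1 or 3 or DT replicate 1, 2 or 4 (0.0564 to 0.102). DT replicate 3 decided the size of most decreases: without it the log2 fold change was -6.09 for Ms4a2, -5.31 for Cyp2e1, -5.17 for C8b and -5.37 for Zfp831. It was -5.25 for Mt4, -5.70 for Pnliprp2, -4.19 for Slc44a5, -4.21 for Mat1a and -4.24 for Ankfn1, and 2741 genes were called, 1369 of them higher. Without DT replicate 4, Hmcn2 had a log2 fold change of 0.94, and 1154 genes were called. Without saline replicate 1 or 4 there were 1196 and 1187 calls, 945 when only the libraries of 48 h were fitted, and 4018 by limma. Without a low-count filter the calls of Gzmd (0.0932) and Defa24 (0.0578) were lost, that of Gzmd also with the leukocyte score as covariate (0.0543), and that of Pnliprp2 with only the libraries of 48 h (0.0825).

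Dividing-cell genes were also higher at 48 h. Of 20 G2/M genes 18 rose (20 adjusted over the list alone; median 0.53, camera adjusted p = 1.5e-20, adjusted p = 0.120 with an estimated correlation). Among them were Ccnb2 (22.6 to 37.2 CPM, 0.72 ± 0.10) and Kif23 (31.7 to 47.7 CPM, 0.59 ± 0.09). Of 22 S phase genes 10 rose (19 adjusted over the list alone; camera adjusted p = 1.6e-09, adjusted p = 0.317 with an estimated correlation). Examples were Rrm2 (0.78 ± 0.18) and Mcm2 (0.35 ± 0.08). Wnt target genes had 10 lower and 1 higher of 21 (14 adjusted over the list alone; camera adjusted p = 2.5e-06, adjusted p = 0.120 with an estimated correlation). Nkd1 (1089 to 697 CPM, -0.65 ± 0.10), Notum (-0.72 ± 0.12) and the homeobox gene Prox1 (913 to 521 CPM, -0.81 ± 0.16) fell and Myc rose (0.51 ± 0.07). The Lgr5+ stem cell list was not called by camera (5 lower, such as Znrf3 with -0.49 ± 0.11, and 1 higher of 21; 6 adjusted over the list alone; camera adjusted p = 0.0958, 0.0496 without saline replicate 3, and called lower by fry, 0.00751). Cholesterol synthesis had 11 lower of 20 (14 adjusted over the list alone; camera adjusted p = 6.0e-10, adjusted p = 0.120 with an estimated correlation). They included Insig1 (-0.58 ± 0.08) and Hmgcs1 (-0.51 ± 0.09). Hypoxia and glycolysis had 8 lower of 15 (9 adjusted over the list alone; camera adjusted p = 8.7e-06, adjusted p = 0.332 with an estimated correlation). Among them were Vegfa (483 to 306 CPM, -0.66 ± 0.12) and the hexokinase Hk2 (-0.35 ± 0.07). With only the libraries of 48 h the calls of Hk2 (adjusted p = 0.0507) and Znrf3 (0.0747) were lost.

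Of 16 EGFR ligand and ERK feedback genes 8 fell at 48 h (10 adjusted over the list alone; camera adjusted p = 1.8e-05, adjusted p = 0.120 with an estimated correlation). Examples were the phosphatase Dusp6 (341 to 262 CPM, -0.38 ± 0.07) and Egr1 (-0.48 ± 0.10). Of 14 immediate early and heat shock genes 9 fell and 1 rose (12 adjusted over the list alone; camera adjusted p = 5.0e-06, adjusted p = 0.198 with an estimated correlation). They included Fosb (-0.60 ± 0.11) and Jun (-0.37 ± 0.07). BMP and TGF-beta targets had 4 lower of 9 (6 adjusted over the list alone; camera adjusted p = 8.3e-04, adjusted p = 0.120 with an estimated correlation). Among them were Id2 (-0.39 ± 0.08) and Smad7 (-0.31 ± 0.07). Antimicrobial genes had 2 lower of 8 (3 adjusted over the list alone; camera adjusted p = 3.1e-04, adjusted p = 0.120 with an estimated correlation). An example was Duox2 (-0.83 ± 0.21). Paneth cell genes had 3 lower of 10 (3 adjusted over the list alone; camera adjusted p = 0.0212, adjusted p = 0.501 with an estimated correlation). They included Defa22 (-2.07 ± 0.46, and -2.82 without DT replicate 3). Of the goblet cell genes Fcgbp fell (299 to 135 CPM, -1.15 ± 0.23). Ly6a (0.79 ± 0.17) and Anxa1 (0.54 ± 0.09) were higher. The type I interferon list had 2 higher, such as Oasl2 (0.66 ± 0.20), and 1 lower, Ifit1 (-0.84 ± 0.21), of 17, and was not called (camera adjusted p = 0.895); B2m was higher (0.60 ± 0.14). The fibroblast list was called higher (median 0.52, camera adjusted p = 0.0138, adjusted p = 0.837 with an estimated correlation) although none of its 12 members was, for example Dcn with 99.6 and 154 CPM (0.63 ± 0.31, adjusted p = 0.199) and Col1a1 with 2109 and 3190 CPM (0.60 ± 0.34, adjusted p = 0.280). The fibroblast call was lost without saline replicate 4 (adjusted p = 0.177) or DT replicate 1 (0.0795) or 3 (0.0694), and the Paneth call without DT replicate 3 (0.0694) or 4 (0.0801). Of the macrophage and monocyte markers Itgam was lower (-0.98 ± 0.31, adjusted p = 0.0437), a call lost without saline replicate 1 or 4 or any DT library (0.0651 to 0.228). The calls of Ifit1 without DT replicate 4 (0.0615), of Oasl2 without any saline library or DT replicate 1 or 2 (0.0556 to 0.0933) and of Duox2 without saline replicate 2 (0.0526) or DT replicate 4 (0.0549) were lost too. So were those of Oasl2 (0.0709) and Itgam (0.111) without a low-count filter, those of Smad7 (0.0707) and Itgam (0.0710) with only the libraries of 48 h, and that of the fibroblast list by fry (0.261). The fetal and regenerative list (camera adjusted p = 0.0958) was called higher without saline replicate 2 (0.0365) or DT replicate 2 (0.0117) and with the leukocyte score as covariate (0.0455). The macrophage and monocyte list (0.130) was called lower without saline replicate 2 (0.0210) or 3 (0.0161) or DT replicate 1 (0.00963). Median and mean differed in sign at 48 h for 7 lists without a call: reserve stem (-0.13 and 0.01, test direction down), enteroendocrine (-0.05 and 0.03, down), type I interferon (-0.06 and 0.01, up), interferon gamma (0.14 and -0.09, up), NF-kB (-0.05 and 0.01, up), Notch (-0.08 and 0.09, up) and neutrophil (-0.07 and 0.30, up).

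At 96 h, 176 genes were higher and 528 lower, 13 and 162 of them by at least 2-fold; with upper quartile scaling the split was 250 higher and 458 lower. Higher genes under the naming rule were the muscle myosin Myh3 (1.66 ± 0.31), the immune checkpoint receptor Havcr2 (1.54 ± 0.34), the sweet taste receptor subunit Tas1r2 (1.52 ± 0.37), the claudin Cldn6 (1.24 ± 0.35), and Atcay (1.14 ± 0.32). Smaller changes were those of the BMP antagonist Smoc1 (1.08 ± 0.27), Enpp2, which makes lysophosphatidic acid (1.01 ± 0.20, from 95.0 to 191 CPM), Fer1l6 (0.94 ± 0.24), the chloride channel Clcn1 (0.91 ± 0.26), Lancl3 (0.88 ± 0.22), Greb1l (0.84 ± 0.21) and the potassium channel Kcnh2 (0.81 ± 0.22). Enpp2 and Myh3 kept their call without each single library and 10 did not. Havcr2 lost it without DT replicate 2 (adjusted p = 0.0756), Tas1r2 without saline replicate 2 or 4 or DT replicate 4 (0.0523 to 0.0798) and Smoc1 without saline replicate 1 or 4 or DT replicate 1, 2 or 4 (0.0501 to 0.0878). Fer1l6 lost it without saline replicate 3 or 4 or DT replicate 1 or 3 (0.0884 to 0.114) and Lancl3 without saline replicate 3 or 4 or DT replicate 1 or 2 (0.0515 to 0.0967). Greb1l lost it without saline replicate 3 or 4 or DT replicate 1, 2 or 4 (0.0525 to 0.0840). Cldn6, Atcay, Clcn1 and Kcnh2 lost it without any 1 library but saline replicate 1 (0.0531 to 0.158). With only the libraries of 96 h it was lost for Havcr2 (0.0606), Tas1r2 (0.0547), Fer1l6 (0.0582), Atcay (0.0559) and Clcn1 (0.111). With the leukocyte score as covariate Cldn6, Atcay, Clcn1 and Kcnh2 lost it (0.0562 to 0.0690), and without a low-count filter Atcay, Clcn1 and Kcnh2 did (0.0660 to 0.0915). Lower genes under the rule were Ms4a2 (-4.46 ± 0.72, from 20.6 to 1.12 CPM), Pnliprp2 (-4.41 ± 0.84, from 567 to 27.6 CPM), Mt4 (-4.06 ± 0.63), C8b (-3.77 ± 0.62), Snhg11 (-3.39 ± 0.54), and Slc4a5 (-3.33 ± 0.54). Then came the intrinsic factor gene Cblif (-3.33 ± 0.54), Pnliprp1 (-3.14 ± 0.59, from 435 to 50.3 CPM), Ankfn1 (-3.04 ± 0.62), Zfp831 (-3.03 ± 0.47), Mat1a (-3.01 ± 0.54) and Spock2 (-3.01 ± 0.45, from 869 to 108 CPM). All 12 kept their call without each single library. Without DT replicate 3 the log2 fold change was -5.59 for Ms4a2, -5.27 for Pnliprp2 and -5.26 for C8b. It was -4.07 for Cblif, -3.91 for Pnliprp1, -3.75 for Ankfn1 and -3.84 for Mat1a, and Cblif had -2.70 without saline replicate 3. Calls numbered 371 and 415 without saline replicates 3 and 4 and 359 and 362 without DT replicates 2 and 4.

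Of 20 G2/M genes 15 were higher at 96 h (20 adjusted over the list alone; median 0.45, camera adjusted p = 3.3e-25, adjusted p = 0.0929 with an estimated correlation). Among them were Ccnb2 (19.1 to 29.2 CPM, 0.60 ± 0.11) and the centromere motor Cenpe (21.6 to 32.6 CPM, 0.59 ± 0.11). The S phase list was called with 1 of 22 members higher, Mcm2 (0.35 ± 0.08; 6 adjusted over the list alone; camera adjusted p = 8.1e-09, adjusted p = 0.413 with an estimated correlation). Of 21 Wnt target genes 7 were lower and 1 higher (11 adjusted over the list alone; camera adjusted p = 1.4e-04, adjusted p = 0.270 with an estimated correlation). Examples were the inhibitor Wif1 (538 to 197 CPM, -1.45 ± 0.26), Nkd1 (-0.50 ± 0.10) and again Myc higher (0.38 ± 0.07). The Lgr5+ stem cell list was not called, with 2 lower of 21, Lgr5 and Znrf3 (-0.38 ± 0.11) (median 0.02, mean -0.01; 4 adjusted over the list alone; camera adjusted p = 0.773). Hypoxia and glycolysis genes had 5 lower of 15 (10 adjusted over the list alone; camera adjusted p = 4.1e-11, adjusted p = 0.152 with an estimated correlation). They included Hk2 (-0.36 ± 0.07) and Vegfa (-0.53 ± 0.12). Immediate early and heat shock genes had 6 lower of 14 (9 adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.152 with an estimated correlation). Among them were Fos (-0.48 ± 0.07) and Fosb (-0.64 ± 0.11). Antimicrobial genes had 3 lower of 8 (5 adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.0929 with an estimated correlation). Examples were the siderophore-binding Lcn2 (-0.78 ± 0.20) and Duox2 (-0.80 ± 0.21). BMP and TGF-beta targets had 1 lower of 9, Smad7 (-0.38 ± 0.07; 5 adjusted over the list alone; camera adjusted p = 6.4e-05, adjusted p = 0.0929 with an estimated correlation). Calls were lost for Znrf3 without any 1 library but saline replicate 2 (0.0850 to 0.159) and for Mcm2 without saline replicate 3 or 4 or DT replicate 2 or 4 (0.0519 to 0.0675). They were lost for Vegfa without saline replicate 3 or DT replicate 2 or 4 (0.0521 to 0.0749) and for Lcn2 without saline replicate 2, 3 or 4 or DT replicate 2, 3 or 4 (0.0694 to 0.0943). Duox2 lost its call without saline replicate 2, 3 or 4 or DT replicate 2 or 4 (0.0789 to 0.135). With only the libraries of 96 h Duox2 (0.135) and Vegfa (0.0654) lost it, and without a low-count filter Lcn2 did (0.0909). The 3 other scalings and the 2 other filters ended the call of Znrf3 (0.0512 to 0.0700), and fry that of the S phase list (0.0770).

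Enteroendocrine cell genes had 1 of 16 higher, the hormone gene Pyy (1.11 ± 0.29, from 3.18 to 6.98 CPM; 1 adjusted over the list alone), with a list median of 0.61 (camera adjusted p = 0.00654, adjusted p = 0.671 with an estimated correlation). Tuft cell genes had none of 17 called (2 adjusted over the list alone; camera adjusted p = 0.00654, adjusted p = 0.671 with an estimated correlation), for example Lrmp with 74.5 and 127 CPM (0.76 ± 0.24, adjusted p = 0.0923) and Hpgds with 10.8 and 16.1 CPM (0.55 ± 0.17, adjusted p = 0.0605). The integrated stress and unfolded protein response list was called lower (camera adjusted p = 0.0153, adjusted p = 0.509 with an estimated correlation) with 3 members lower, such as Atf3 (-0.57 ± 0.09), and 2 higher, such as the cystine transporter Slc7a11 (0.64 ± 0.14), of 15 (6 adjusted over the list alone). Outside the called lists, Hes1 of the Notch list was higher (0.42 ± 0.10), and Fcgbp (-0.89 ± 0.23) and Defa22 (-2.56 ± 0.51) were lower. The type I interferon list had no member of 17 called by edgeR (3 adjusted over the list alone; camera adjusted p = 0.604, and 0.0411 without DT replicate 2). Calls were lost for Pyy without saline replicate 2 or 4 or DT replicate 1, 3 or 4 (adjusted p = 0.0659 to 0.105) and for Fcgbp without saline replicate 1, 3 or 4 or DT replicate 1, 2 or 4 (0.0572 to 0.118). The call of Hes1 was lost without saline replicate 4 (0.0575). With only the libraries of 96 h those of Pyy (0.0518) and Fcgbp (0.107) were lost, and that of Fcgbp also without a low-count filter (0.0716). DESeq2 and limma called Lrmp (0.0190 and 0.00477) and Hpgds (0.0229 and 0.0333). By fry the enteroendocrine (0.357), tuft (0.282) and stress response (0.0649) lists were not called. The enteroendocrine call was lost without saline replicate 2 (0.112) or DT replicate 3 (0.538) and the tuft call without saline replicate 2 (0.337) or DT replicate 4 (0.128). The stress response call was lost without saline replicate 2 (0.0742) or 3 (0.0776) or DT replicate 2 (0.0563). Some lists without a call at 96 h were called when 1 library was left out. Lower were Paneth genes without saline replicate 2 or 4 or DT replicate 3 (0.00429, 0.0450 and 0.00152, against 0.0854) and EGFR and ERK genes without saline replicate 1 or DT replicate 3 (0.0206 and 0.0181, against 0.0854). Without saline replicate 1 the NF-kB (0.00706, against 0.444) and macrophage (0.0370, against 0.256) lists were lower too, and the enterocyte list was higher without DT replicate 1 or 2 (0.0146 and 0.0421, against 0.117). The test direction was up while the median was below 0 for the reserve stem (-0.02, mean 0.07), fetal (-0.02, mean -0.02), cholesterol (-0.04, mean 0.01), epithelial identity (-0.01, mean -0.01) and fibroblast (-0.04) lists at 96 h, and for Notch (-0.01). By DESeq2 and limma the overall counts of calls at 96 h were 928 and 1581.

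The comparison among times asked which DT effects changed between 24 and 96 h. An interaction test over the 3 times called 1392 genes. All 17 type I interferon genes, 18 of 20 G2/M genes, 17 of 22 S phase genes, 8 of 17 interferon gamma genes and 9 of 20 cholesterol synthesis genes differed among times. None of 16 EGFR ligand and ERK feedback genes, 9 BMP targets or 15 hypoxia genes passed this test over the 3 times, although 2 of the BMP targets and 3 of the hypoxia genes differed in DT effect at 96 h against 24 h. The effect was lower at 48 h than at 24 h in 16 of the 17 type I interferon genes. The genes given of those with the smallest p are Nr1d1, a circadian repressor (log2 fold change 2.38, 1.33 and 0.33 at 24, 48 and 96 h), Oas3 (3.87, 0.34 and 0.65) and the replication factor Mcm10 (1.61, 0.64 and 0.35). Next were Oas1g (2.77, 0.46 and 0.26) and Oas1a (2.70, 0.59 and 0.55). The others were the antiviral membrane protein Bst2 (2.64, 0.40 and 0.30), Parp9 (0.92, 0.12 and 0.12), Ppp1r10 (1.41, 0.73 and 0.15) and Isg15 (1.88, -0.09 and -0.15). Oas1a and Oas1g are close copies, and Nr1d1 lies against Thra on the opposite strand, so that their reads cannot be told apart where the counting did not use strand. Between pairs of times, 505 genes differed in DT effect at 48 h against 24 h (97 with a higher and 408 with a lower effect at 48 h) and 2079 at 96 h against 24 h (713 and 1366). Only Nr1d1 was called between 96 and 48 h (log2 fold change 1.33 and 0.33, edgeR quasi-likelihood adjusted p = 0.0357). There 1057 genes had an unadjusted p under 0.05 and DESeq2 and limma called 14 and 21. No gene (0) was called with the leukocyte score as covariate or with only the libraries compared. The count was also 0 without any saline library of 48 h, DT replicate 1 or 4 of 48 h, saline replicate 2, 3 or 4 of 96 h, or DT replicate 1, 2 or 4 of 96 h. Without DT replicate 3 of 48 h the 1 gene called was not Nr1d1, and without DT replicate 2 of 48 h or DT replicate 3 of 96 h the count was 2. The interaction count was 2181 by limma, and 840 and 887 without saline replicates 2 and 4 of 24 h. The count for 48 h against 24 h was 772 by DESeq2, 925 by limma and 315 with only the libraries compared. It was 325, 272 and 336 without saline replicates 1, 2 and 4 of 24 h. The same count was 323 without saline replicate 4 of 48 h, 865 without DT replicate 1 of 48 h and 321 without DT replicate 3 of 48 h.

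Calls at different times overlapped in direction. Both 24 and 48 h had 774 genes higher, against 167.6 for independent lists of those sizes, and 1028 lower, against 214.2; 6 were called in opposite directions. The 24 and 96 h comparisons shared 144 higher genes (35 for independent lists) and 459 lower (99.6), with 5 opposite. Those of 48 and 96 h shared 92 higher (8.5) and 399 lower (34.3), with 0 opposite. These comparisons use different saline libraries. Across genes, which are not independent replicates, log2 fold changes correlated with Pearson's r of 0.748 between 24 and 48 h, 0.543 between 24 and 96 h and 0.597 between 48 and 96 h.

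Saline libraries alone were compared among the 3 times as the background. Here 184 genes differed. The genes with the smallest p, named after their values were seen, were the heat shock gene Hspa1b, with mean CPM of 552, 83.9 and 165 at 24, 48 and 96 h (adjusted p = 4.3e-11), Fosb (597, 1339 and 1524 CPM), the small heat shock protein gene Cryab (36.3, 15.2 and 16.1 CPM) and Fos (1349, 2249 and 2366 CPM). DESeq2 called 647 and limma 811 genes, 648 were called with a leukocyte marker score as covariate, and leaving out single libraries gave 62 to 790. The count was 82, 62, 98 and 66 without saline replicates 1 to 4 of 24 h, and 790, 77, 109 and 100 without replicates 1 to 4 of 96 h. Markers of other cell types moved among these times. Of 8 endothelial markers 4 differed (8 adjusted over the list alone), such as Tek (9.41, 12.8 and 17.2 CPM, adjusted p = 0.0311), and all 8 had a higher mean at 96 h than at 24 h. Of 12 macrophage and monocyte markers Lyz2 differed (195, 104 and 59.5 CPM, adjusted p = 0.0347; 9 adjusted over the list alone), and none of the 12 had a higher mean at 96 h than at 24 h. The calls of Tek and Lyz2 were lost without any saline library of 24 h or replicate 2, 3 or 4 of 96 h (0.0599 to 0.126 and 0.0512 to 0.108). Of 10 goblet cell genes 3 differed (5 adjusted over the list alone), such as Tff3 (10.1, 3.7 and 2.3 CPM, adjusted p = 0.00560), all with a lower mean at 96 h. Tek, Lyz2 and Tff3 were chosen after their values were seen.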

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

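Tests of the splits by treatment were planned; the redraws of the times were added after those were seen. Of 344 sets of 4 values, each a named gene or the total count in 1 group, 36 had a library standing apart. Its gap to the nearest other exceeded Dixon's critical share of the range. Chance would give about 1 set in 20, or 17.2, if the sets were independent. Values of 1 library are related across genes, and 9 of the 36 fall on DT replicate 3 of 48 h. The count of 36 against 17.2 is therefore no test. The gap as a share of the range, in CPM, is given for each gene. In DT replicate 3 of 48 h it was 0.902 for Ms4a2, 0.945 for Cyp2e1, 0.953 for C8b, 0.932 for Zfp831, 0.851 for Mt4, 0.957 for Pnliprp2, 0.875 for Slc44a5, 0.907 for Defa22 and 0.916 for Vegfa. In DT replicate 3 of 96 h it was 0.974 for C8b, 0.936 for Cblif, 0.847 for Pnliprp1, 0.931 for Mat1a and 0.920 for Hes1. The gap was 0.915 for Ampd1, 0.866 for Ankfn1 and 0.862 for Etv5 in saline replicate 1 of 24 h, 0.857 for Atf4, 0.841 for Slc2a1 and 0.915 for Hbegf in saline replicate 2 of 24 h, 0.843 for Hmcn2 and 0.883 for Gzmd in DT replicate 4 of 48 h, 0.901 for Zglp1 and 0.848 for Egr1 in saline replicate 1 of 48 h, 0.918 for Dusp6 and 0.835 for Col1a1 in saline replicate 4 of 48 h. The gap was 0.843 for Snhg11 and 0.860 for Pnliprp1 in saline replicate 2 of 96 h, 0.908 for Atf4 in DT replicate 2 of 24 h, 0.971 for Ctrb1 in DT replicate 3 of 24 h, 0.937 for Notum in DT replicate 4 of 24 h, 0.841 for Lcn2 in DT replicate 1 of 96 h. The gap was 0.913 for Mcm3 in saline replicate 3 of 24 h, 0.834 for Pnliprp2 in saline replicate 3 of 48 h, 0.899 for Enpp2 in saline replicate 1 of 96 h, 0.903 for Cblif in saline replicate 3 of 96 h.

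The DT effect differed among the times by the interaction test for 45 of 123 genes, 36 of them with a lower effect at 96 than at 24 h. These 123 genes are those the text names, which include the largest effects at 24 h and genes with the smallest interaction p, so the choice partly sets both counts; over all 17468 genes tested 1392 differed. The value is the log2 effect at 96 h minus that at 24 h. It was -4.87 for Cxcl9, -3.23 for Oas3, -2.67 for Tnfsf15, -4.79 for Ucp1, -3.81 for Trp53cor1, -3.26 for Aloxe3, -3.14 for Ifit3, -2.94 for Myo15, -1.39 for Ly6a, -0.55 for Anxa1, -1.22 for Ankrd1, -0.91 for Uhrf1 and -0.82 for Mcm3. For other genes with a lower effect at 96 h it was -1.60 for Rrm2, -0.96 for Ccnb2, -0.84 for Kif23, -0.96 for Bub1, -2.03 for Isg15, -2.12 for Oasl2, -1.0 for B2m, -1.48 for Tap1, -0.87 for Psat1, -0.62 for Atf4, -1.91 for A3galt2 and -3.17 for Zglp1. For the remaining lower ones it was -1.56 for Ephx3, -0.51 for Mcm2, -0.87 for Ifit1, -0.63 for Cenpe, -2.06 for Nr1d1, -1.26 for Mcm10, -2.52 for Oas1g, -2.15 for Oas1a, -2.34 for Bst2, -0.80 for Parp9 and -1.26 for Ppp1r10. Where the effect at 96 h was the higher, it was 0.86 for Lgr5, 0.39 for Rnf43, 0.63 for Nkd1, 0.75 for Notum, 2.07 for Muc2, 2.22 for Reg3b, 0.75 for Insig1, 0.71 for Hmgcs1 and 1.58 for Havcr2.

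Other splits of the same libraries bear on whether chance gives as many genes. At 24 h 1 of 35 splits, the real one, gave 6765 genes and the next highest 362. At 48 h 1 of 35 gave 1979 and the next 358, and at 96 h 1 of 35 gave 704 and the next 5. At each time the next highest split exchanged 1 library of each group. A chance split of these libraries is therefore unlikely for these 3 counts, though 1 of 35 is the smallest share that these splits can give. Where the libraries of a group do not come from separate animals, the splits cannot exclude chance differences between animals. For differences among times, 8 of 100 redraws of treatment within times gave at least the 1392 genes observed (highest other 5602), 8 of 100 the 505 for 48 against 24 h (6489) and 8 of 100 the 2079 for 96 against 24 h (5046). The highest of these are several times the real counts. Such a redraw may keep the DT effect at 1 time and mix or reverse it at another, which itself makes a difference among times. This scheme therefore cannot decide whether chance gives the real counts. Of the 7 other redraws as large, 5 had 1 time mostly swapped between treatments, which turns a DT effect into a difference among times. These 5 are of 28 redraws with a time so swapped, so such a swap does not by itself give as many genes. Redrawing the times within each treatment gave at least as many genes in 3 of 100 (highest other 2466), 5 of 100 (2100) and 2 of 100 (3673). As many genes were thus rare by this scheme, least so for 48 against 24 h. Since it was added after the other scheme had been seen, and that other scheme cannot decide, chance is not excluded for these counts. For 96 against 48 h, with 1 gene called, these were 2 of 100 (1) and 8 of 100 (3262), so the schemes differ. Among saline times 2 of 100 gave at least 184 (highest other 215), so as many genes were rare in these redraws. Each time is 1 set of libraries, so a redraw cannot tell time from other differences between the sets.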

How the results depend on the processing

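Scaling by the authors' size factors was chosen after the data were seen, and all other alternatives were planned. Over the alternatives run on them the named genes kept their side of the threshold in 6278 values, passed below it in 382 and above it in 109. Gene lists were run only with median-of-ratios scaling, the replicate block, the leukocyte covariate, an estimated correlation, fry and single libraries left out. Their counts were 1208, 52 and 24. Direction was not checked where neither value was called. No call of DT against saline at 24, 48 or 96 h changed sign without a library. At a depth of 10.9 to 27.7, in units of 1e6 counts, and 4 libraries per group, the simulated test recovered 63% of 1.5-fold changes at 24 h and 48% for the interaction. Neither depth nor group size was varied. The simulation changed 200 genes, against 6765 called in the data at 24 h, so these shares need not hold for the data. With a log2 fold change of at least 1, fewer genes pass by construction: 1065, 295 and 175 at 24, 48 and 96 h, 94 for 48 against 24 h and 328 for 96 against 24 h. For the following changes the cause was not tested. limma voom with quality weights called 4018 genes at 48 h, 1581 at 96 h, 925 for 48 against 24 h, 21 for 96 against 48 h, 2181 among times and 811 among saline times. DESeq2 called 772 for 48 against 24 h, 14 for 96 against 48 h and 647 among saline times. With only the libraries compared, 945 genes were called at 48 h, 315 for 48 against 24 h and 0 for 96 against 48 h, and Lgr5 at 48 h had -0.595. The leukocyte covariate gave 648 among saline times, 0 for 96 against 48 h and -0.439 for Lgr5 at 96 h. Lgr5 at 96 h also missed the threshold with median-of-ratios (-0.422), upper quartile (-0.409) and the authors' (-0.423) scaling and no filter (-0.425). Lists called went from 14, 11 and 10 to 2, 0 and 0 with an estimated correlation, and to 6 at 96 h with fry. Calls shared in direction with an adjusted p under 0.1 were 921 for 24 and 96 h and 748 for 48 and 96 h.

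Without 1 library at a time, calls ranged from 5961 to 6729 at 24 h, 1154 to 2741 at 48 h, 359 to 680 at 96 h, 272 to 865 for 48 against 24 h, 1577 to 2369 for 96 against 24 h, 0 to 2 for 96 against 48 h, 840 to 2070 among times and 62 to 790 among saline times. Lgr5 ranged from -1.360 to -1.263 at 24 h, -0.803 to -0.501 at 48 h and -0.470 to -0.398 at 96 h. Lists called ranged from 13 to 15, 9 to 13 and 8 to 13.

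Replicate numbers did not pair the samples: same-number correlations ran from -0.356 to 0.130, and not every sample correlated best with its own number. With the replicate number as a block, calls were 933 at 48 h, 301 at 96 h, 172 for 48 against 24 h, 1014 for 96 against 24 h, 0 for 96 against 48 h, 476 among times and 7 among saline times, and Lgr5 at 96 h had -0.432 (adjusted p = 0.152).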

Other observations

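The gene lists of the first paragraph and their tests were chosen after gene tables had been seen. For the patterns that follow, the tests of leukocytes and of the library standing apart were written after the result was seen; the scaling, acinar and mast cell tests were written before it, but for a set of 120 genes, and narrowed to Pnliprp2 and Ms4a2 afterwards. All 20 ribosome biogenesis genes were higher in DT libraries at 24 h (median log2 fold change 0.62, camera adjusted p = 7.4e-24, adjusted p = 0.00938 with an estimated correlation), including the nucleolar proteins Nop56 (1.13 ± 0.07, 85.0 to 186 CPM) and Mybbp1a (0.76 ± 0.05). Of the 20, 12 were higher at 48 h (2.2e-15, adjusted p = 0.0436 with an estimated correlation) and 5 at 96 h (5.5e-09, 0.221 with an estimated correlation). Of 20 cytosolic aminoacyl-tRNA synthetases 16 were higher at 24 h, such as Vars (0.82 ± 0.06; camera adjusted p = 2.1e-08, adjusted p = 0.193 with an estimated correlation), and of 18 oxidative phosphorylation genes 14, such as Uqcrc1 (0.62 ± 0.07; 8.8e-07, 0.356 with an estimated correlation). At 48 h 6 of the synthetases were higher (camera adjusted p = 7.3e-05, adjusted p = 0.365 with an estimated correlation) and 5 of the oxidative phosphorylation genes (1.3e-06, 0.365 with an estimated correlation). At 96 h 0 synthetases were higher and 1 lower (0.455), and 0 oxidative phosphorylation genes were called (0.114). Of 16 circadian clock genes 7 were higher and 4 lower at 24 h (camera adjusted p = 0.0901). The higher ones included Nr1d1 (2.38 ± 0.12), Dbp (0.76 ± 0.11) and Per1 (0.61 ± 0.11). Nfil3 (-0.71 ± 0.08), Cry2 (-0.65 ± 0.14), Per3 (-0.36 ± 0.14) and Bhlhe40 (-0.27 ± 0.09) fell, and Per2 had -0.05 ± 0.14 (edgeR adjusted p = 0.805). Clock genes higher and lower were 2 and 2 at 48 h (camera adjusted p = 0.117) and 0 and 3 at 96 h (0.114). Liver markers had 1 higher and 3 lower of 10 at 24 h (camera adjusted p = 0.278), 1 and 1 at 48 h (0.795) and 0 and 2 at 96 h (0.114).

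A set of 120 genes was at least 2-fold lower and called at all 3 times, against 2 genes at least 2-fold higher (382 and 89 with no fold limit), with medians of -2.14, -1.68 and -1.74 at 24, 48 and 96 h. Pancreatic acinar cells in the saline libraries are argued against for Pnliprp2, since the acinar markers summed to 85.58 CPM in saline at 24 h, below Pnliprp2 in all 4 libraries. The mast cell test for Ms4a2 used only Cpa3, which had 0.63 CPM, below Ms4a2 in all 4. The 8 mast cell markers measured summed to 76.64 CPM there, mostly Kit (45.57 CPM) and Tpsb2, above the 24.14 CPM of Ms4a2. In DT libraries of 24 h the sum was 92.41 CPM, and Kit was called higher (78.32 CPM, log2 fold change 0.775 ± 0.301, edgeR adjusted p = 0.0475). These values go against a loss of mast cells, whereas the fall of Tpsb2 goes with it. Of the 8 markers 1 was called higher and 1 lower. Mast cells therefore stay open for Ms4a2. The mast cell gene Tpsb2 is itself in the set (21.2 to 2.19 CPM at 24 h, -3.18), although the 8 mast cell and 4 acinar markers measured were not called as lists (0.750 each). The other scalings kept at least 118 of the 120 genes. A loss together with the Lgr5-expressing cells, a loss of other cells, or a change within the remaining cells may account for the set; since its genes were chosen as at least 2-fold lower at each time, setting their size against that of Lgr5 decides nothing, and these stay open.

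Type I interferon genes were higher at 24 h, with a lower quartile of 1.08 and a median of 1.62. More leukocytes in the DT libraries are argued against by the upper quartile of 21 leukocyte markers, 0.359, and Ptprc, a leukocyte surface gene, had 8.32 CPM in saline and 6.90 CPM in DT libraries. Under the other scalings at least 16 of 17 members stayed called. Induction within leukocytes already present, or within the tumour cells, may account for it and stays open. The toxin itself is open as well, since no group here received toxin without its target.

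On a score of the genes at least 2-fold changed at 24 h, set to 0 at the mean of the saline libraries of 48 h and 1 at that of the other DT libraries of that time, DT replicate 3 of 48 h lay at 0.555, the other 3 at 0.937 to 1.052. A swap with a saline library of 48 h is argued against by the highest of these, 0.129, and a saline sample under a DT label by the 12 saline libraries, which lay between -0.334 and 0.185 (SD 0.147). Its Lgr5 of 171 CPM, within the saline range, goes the other way. A smaller effect of the toxin in this sample, or a mixture, may account for its place, and DT libraries of 96 h lay at 0.570 to 0.728.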
